A study of Rattus norvegicus with 12 samples.

How the data were processed

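Gene expression was measured in rat tissue on 12 one-colour Applied Biosystems arrays hybridized with digoxigenin-labelled cRNA. The samples came from Brown Norway (BN) and Sprague Dawley (SD) rats. Each strain had a sham-operated control group and a group given 45 min of bilateral renal ischemia and 24 h of reperfusion (I/R), with 3 arrays in each of the 4 groups, which the labels call biological replicates. The labels speak of tissue without naming the organ. They also mention replicate arrays of several RNAs, without saying which arrays these are. Each n below therefore counts arrays, and where arrays share an RNA the p-values measure partly technical spread.

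Per the file headers, the deposited scanner files give for every feature a signal intensity, an assay-normalized signal intensity, a signal-to-noise score and a quality flag. The intensity is on a linear scale, differs in median between arrays and was not normalized between arrays, while the deposited assay-normalized intensity is, within rounding, that signal divided by a constant per array. The deposited signal-to-noise score and the flag come from the scanner software, and its version is not given in the sources used here. The 12 deposited array files are 3 distinct files, each of which holds the 4 arrays of 1 replicate number. The columns of the replicate 3 file carry strain and condition but no number. The authors also deposited a value table on a log2 scale with 16341 rows. Set against the scanner signal, it held 15942 probes for replicates 1 and 2, and 13324 for replicate 3. All of these had a signal-to-noise score of at least 3 on at least 2 arrays of their set, a filter applied to replicate 3 apart from the others. The median of each value table column lay between 11.92 and 12.02, and the method by which the authors normalized it is not given in the sources used here. For 10 of its 12 columns the best correlated scanner array was the column's own (r of at least 0.9976 across probes), and for the control columns BN replicate 2 and SD replicate 1 it was each other's. The scanner signal was therefore used throughout, with the value table as an alternative.

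Groups and replicate numbers were taken from the sample titles. The source names of BN control replicate 3 and SD control replicate 3 say I/R, and the descriptions of SD control replicates 2 and 3 say Brown Norway. The titles were kept, because the names of the scanner columns match them, and fits without these arrays were run as alternatives. Leaving out all 3 arrays left a single SD control array, so in that fit the spread comes from the other groups and a lost call is weak evidence.

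The files hold 27179 features, of which 322 control spots were left out, leaving 26857 measurement probes. Of these, 26800 carry an rCG gene identifier and 57 a RefSeq accession. The files do not pair rCG identifiers with gene names. Through RefSeq gene names of the GRCr8 assembly, 34 of the accessions and 1 rCG identifier matched a symbol, which gave 35 probes of 34 genes. Of the 844 genes in 37 lists of pathways and cell types fixed before the data were examined, 5 were measured by name, with at most 1 in any list. Lists of under 5 measured genes were not to be tested, so no list was tested. Kidney injury genes chosen in advance, such as Havcr1 and Lcn2, were not among the genes measured by name and were not analysed here.

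Signals were quantile-normalized between the 12 arrays, floored at the 5th percentile (a signal of 204.6) and taken to log2. A probe counted as detected with a signal-to-noise score of at least 3 and a flag below 5000, and the 15401 probes detected on at least 3 of the 12 arrays were tested. Arrays detected between 10790 and 14922 probes. The number of arrays limits the precision of every comparison. limma 3.58.1 in R 4.3.3 fitted 1 mean per group with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Strain differences are given as BN minus SD and responses as I/R minus control. Python 3.11.15 read the files and drew the figures.

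The numbers pair the samples: arrays of the same number share a deposited file, and their deviations from the group means correlated in all 18 pairs (r from 0.393 to 0.7), against -0.575 to 0.254 in the 36 pairs of different numbers and groups. All 12 arrays correlated best with an array of their own number. A fit with the replicate number as a block (6 residual degrees of freedom) is therefore given beside each count that it moved by over 1.5 times. The run marks in the scanner headers coincide with the replicate number, so no separate block for them could be fitted. The terms run and replicate number mean the same below.

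On simulated data with the real probe means, run shifts and the residual spread of the fit with the block described above, 200 of 15401 probes were changed in BN after I/R. At a simulated log2 change of 1, 0 of the 200 were recovered without the block and 1 with it. At 2, the numbers were 18 and 153, and at 3 they were 130 and 191. False calls were 0 without the block and at most 10 with it. The simulated noise was drawn independently for each array, with the same spread on all arrays, and no strain difference was simulated. Recovery and false calls on the real arrays can therefore differ from these numbers.

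Among named genes, the rule fixed before the data were examined took the 10 largest rises and 10 largest falls past the threshold in each comparison, detected on every array of at least 1 group and without overlap between the arrays of the groups. Where none passed, it took the 5 smallest p-values in each direction. No named gene passed in any of the 5 comparisons, and 6 genes met the condition on detection. Probes without a gene name are given by identifier, at most 2 higher and 2 lower in a comparison, and were chosen after their values were seen, as the largest changes among called probes. Where a probe was detected on no array of the dimmer group, its difference is a bound, the mean of the brighter group over that of the dimmer one, in which each dim array is given the lowest signal among its detected probes or the probe's own signal if that is higher. Such a bound concerns the group means and does not cover the spread between arrays or runs. Where only some arrays of a group detected it, the others entered the fit at their measured signal although it was not above background, so the difference can be understated. Alternatives covered the normalization, the floor, the background correction, the filter, the spread, the array weights, the block and each array in turn.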

Results

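The data comprised 12 arrays, 3 from each of BN controls, BN after I/R, SD controls and SD after I/R. Median signals lay between 502.3 and 1209 before normalization. The arrays of replicate 1 detected 10790 to 11992 probes, those of replicate 2 14494 to 14922 and those of replicate 3 12633 to 13554. Replicate number separated the arrays more than strain or condition did, with 55.5% of the variance of the tested probes lying between replicate numbers and 21.8% between the 4 groups. These shares make no allowance for the number of groups. Arbitrary groups of arrays also hold some variance, so the 21.8% does not measure an effect of strain or I/R.

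The strains were first compared in control animals. Strain differences here and below are differences in probe signal, and whether transcript levels differed was not tested by another measure. The widest difference was that of the rCG50417 probe, at a mean log2 signal of 16.72 ± 0.43 (SD, n = 3) in SD controls and detected on none of the 3 BN control arrays. On the group means this puts it at least 209-fold higher in SD. Within runs 1, 2 and 3 its log2 differences were -9.02, -8.45 and -5.98. rCG58615 was lower in BN, where 1 of 3 control arrays detected it, by a fitted log2 difference of -5.97 ± 0.67 (SE; limma adjusted p = 0.00907). In the opposite direction, rCG57998 reached 16.02 ± 0.18 in BN and 10.07 ± 1.04 in SD (SD, n = 3), where 2 of 3 arrays detected it, a fitted 61.7-fold difference with an adjusted p of 0.000422. rCG25170 was detected on all 3 BN and none of the SD control arrays. On the group means it was at least 42.2-fold higher in BN, with a limma adjusted p of 0.000422. Its log2 differences within the runs were 6.5, 5.38 and 4.6. Each of these 4 differences had the same direction within all 3 runs. They did not pass in the value table as deposited, but 2 control columns of opposite strains appear exchanged there, so it cannot test them. None of the 4 differences passed without replicate 2 in all groups. That of rCG58615 also did not pass without replicate 1 or 3, without SD control replicate 3 or without the control arrays of contradicting labels, that of rCG50417 without replicate 1 and that of rCG57998 without replicate 3. The fitted fold moved by over 1.5 times for rCG50417 without replicate 1 or 3 or BN control replicate 3, for rCG57998 without SD control replicate 1, and for 3 of the 4, not rCG58615, without the 3 control arrays of contradicting labels. In all, 15 of 15401 probes differed by limma, 10 higher and 5 lower in BN. With the replicate block 70 differed, 33 higher and 37 lower, and these included the 15. With median scaling the unblocked split was 6 higher and 8 lower, and with the assay-normalized signal 5 and 4. In the value table with the 2 exchanged columns put back, 13 passed without the block, 8 higher and 5 lower, 10 of them among the 15. With the block, 118 passed there, 66 of them among the 70. The unblocked count was 4 without replicate 1 or 3 and 0 without replicate 2 (321 at an unadjusted p under 0.05), and 4 to 9 without BN control replicate 1, 2 or 3, SD control replicate 1, 2 or 3, BN I/R replicate 2 or SD I/R replicate 2. With the block it was 4, 0 (1034 unadjusted) and 25 without replicates 1, 2 and 3, and 21 to 43 without any 1 array other than SD I/R replicate 3.

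**Figure D1:**
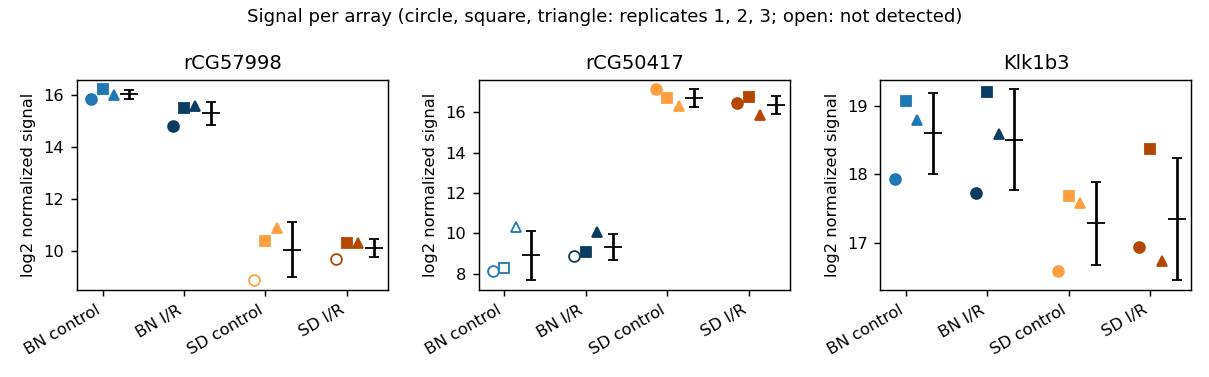
Normalized log2 signal (vertical axis) of rCG57998, rCG50417 and Klk1b3 on each of the 12 arrays by group (horizontal axis); symbols mark replicates 1, 2 and 3, open symbols a probe that was not detected, and bars the mean and SD of 3 arrays. The 6 BN arrays lie above the 6 SD arrays for rCG57998 and below them for rCG50417, while for Klk1b3 the BN and SD arrays overlap after I/R but not among the controls, as chance gives for 10% of probes with 3 arrays against 3.

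Klk1b3, a kallikrein-related serine protease, had the smallest p among named genes in this comparison. Its log2 signal was 18.6 ± 0.58 in BN and 17.29 ± 0.6 in SD controls (SD, n = 3), a difference of 1.31 ± 0.55 (SE) that did not pass (adjusted p = 1, and 0.123 with the replicate block). In the value table as deposited, where 2 control columns of opposite strains appear exchanged, the difference was -0.32. Ramp2, a receptor activity-modifying protein of endothelium, differed by 0.71 ± 0.58 and the beta-globin gene Hbb-b1 by 0.73 ± 0.72. The integrin alpha E gene Itgae differed by 0.46 ± 0.39, while the stress-response transcription factor gene Atf4 differed by -0.38 ± 0.29 and Cebpb, a transcription factor of the acute-phase response, by -0.07 ± 0.45. None of these passed, and the value for Cebpb was 0.1 with median scaling and 0.2 with the assay-normalized signal.

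After I/R, 3 of these 4 probes were again among the widest differences. rCG50417 was 132-fold lower in BN, where 2 of 3 arrays detected it, with a log2 difference of -7.05 ± 0.58 (SE; adjusted p = 0.00152). rCG58615, also detected on 2 of 3 BN arrays, was lower by a log2 difference of -5.76 ± 0.67, with an adjusted p of 0.00861. rCG57998 was 36-fold higher in BN, with an adjusted p of 0.00265, and 2 of 3 SD arrays detected it. rCG49940 was higher in BN by a fitted log2 difference of 4.07 ± 0.46 (SE; adjusted p = 0.00749), and 1 of 3 SD arrays detected it. In all, 7 probes passed, 5 higher and 2 lower in BN, and 6 of them were also among the 15 of the controls, in the same direction. Independent lists would share 0.00682 in either direction. With the replicate block 38 passed, 23 higher and 15 lower. These shared 23 probes with the 70 of the blocked control comparison, all 23 in the same direction, against 0.173 in either direction for independent lists. Both comparisons share 1 residual spread per probe within a fit, so their lists are not independent and these expected values are only a rough reference. With median scaling the unblocked split was 4 higher and 5 lower, and with the assay-normalized signal 4 and 4. In the value table with the 2 exchanged columns put back, 7 passed without the block, 5 higher and 2 lower, 6 of them among the 7 here. With the block, 56 passed there, 37 of them among the 38. The unblocked count was 1 without replicate 1 or 3 and 0 without replicate 2 (387 at an unadjusted p under 0.05). With the block it was 2 without replicate 1 or 3, 0 without replicate 2 (1258 unadjusted), 10 to 15 without any 1 of the 6 I/R arrays or BN control replicate 2, 21 without BN control replicate 1 and 24 without SD control replicate 1. In the value table as deposited, whose exchanged control columns enter the shared residual spread, the calls of all 4 probes were lost. The calls of all 4 were also lost without replicate 2. Those of rCG58615 and rCG49940 were also lost without replicate 1 or 3, with only their own groups and without the 3 control arrays of contradicting labels, that of rCG50417 without replicate 1, that of rCG57998 without replicate 3, and that of rCG58615 without BN I/R replicate 2 or SD I/R replicate 2. The fold moved by over 1.5 times for rCG50417 without replicate 3 and for rCG58615 without SD I/R replicate 1. Klk1b3 differed by 1.16 ± 0.55 (SE), Hbb-b1 by 0.57 ± 0.72, Ramp2 by 0.44 ± 0.58, Itgae by 0.15 ± 0.39, Atf4 by -0.22 ± 0.29 and Cebpb by -0.37 ± 0.45, and none of them passed.

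The response to I/R was then examined within each strain. In BN rats, no probe passed by limma without the block (427 of 15401 at an unadjusted p under 0.05). With the replicate block 7 probes passed, 5 higher and 2 lower. Of these, rCG21543 rose from 11.2 ± 0.15 to 13.32 ± 0.16 (SD, n = 3), a 4.35-fold rise with an adjusted p of 0.0183. rCG29574 rose 3.47-fold (adjusted p = 0.0359), with log2 changes of 2.01, 1.76 and 1.61 within the 3 runs. In the fit without the block, its log2 change ran from 1.06 without BN control replicate 1 to 2.43 without BN I/R replicate 1. Those fits leave the other BN array of replicate 1 unpaired, so the range includes the difference between runs. rCG20852 was detected on all 3 control arrays and on none after I/R, at least 6.69-fold lower (adjusted p = 0.0183), and rCG23883 was 3.41-fold lower (adjusted p = 0.0183). All 4 changed in the same direction in each of the 3 runs. With the block as a random effect, rCG29574 and rCG23883 did not pass (adjusted p = 0.151 and 0.113). With the block and median scaling 3 passed, 1 higher and 2 lower. The BN responses of replicates 1 and 2 correlated at r = 0.807 across the 7076 probes with a signal-to-noise score of at least 5 on every array, while that of replicate 3 correlated with them at 0.14 and 0.144. Genes and probes are not independent replicates in such a correlation. With the block, 126 probes passed without the BN I/R array of replicate 3, among them the 7, 71 without both BN arrays of replicate 3, among them 4 of the 7, and 54 without replicate 3 in all groups, among them 1 of the 7. The blocked count was 0 without replicate 1 (572 at an unadjusted p under 0.05) or 2 (774), without BN control replicate 1, 2 or 3, without BN I/R replicate 1 or 2, and without SD control replicate 1 or SD I/R replicates 2 or 3. It was 2 without SD control replicate 3 and 4 without SD I/R replicate 1.

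**Figure D2:**
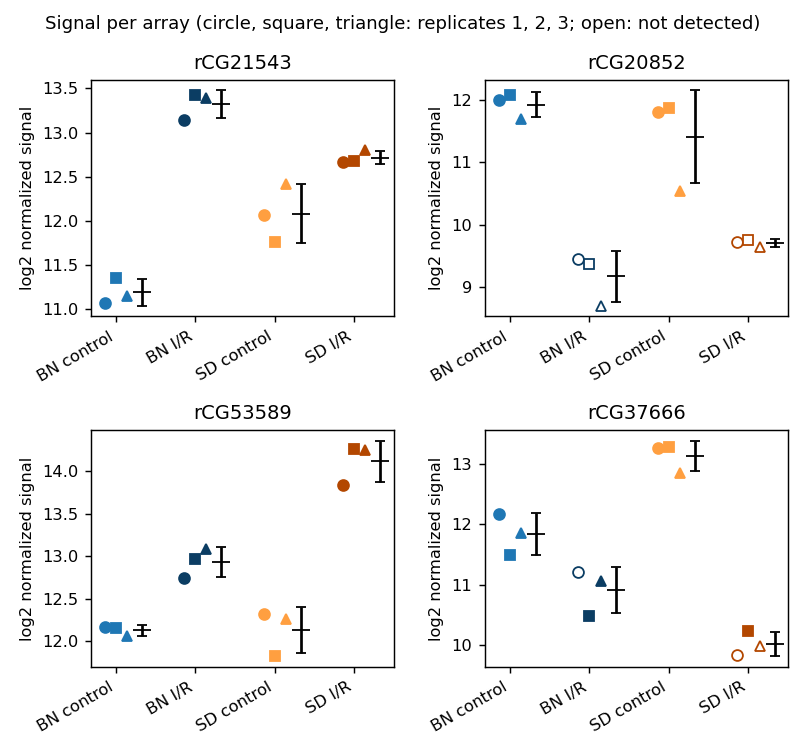
Normalized log2 signal (vertical axis) of rCG21543, rCG20852, rCG53589 and rCG37666 on each of the 12 arrays by group (horizontal axis); symbols mark replicates 1, 2 and 3, open symbols a probe that was not detected, and bars the mean and SD of 3 arrays. rCG21543 rises from 11.2 to 13.32 in BN, and rCG37666 falls from 13.14 in SD to a level that 1 of 3 arrays detected.

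In SD rats, 1 probe passed without the block, rCG37666, which fell from 13.14 ± 0.25 (SD, n = 3) to a level that 1 of 3 I/R arrays detected. Its fitted log2 change was -3.13 ± 0.32 (SE), and -3.27 to -2.96 when an array or replicate was left out. The limma adjusted p was 0.0147, and 772 probes had an unadjusted p under 0.05. With the replicate block 5 probes passed, 3 higher and 2 lower, this one included, and with the block and median scaling 22, 11 higher and 11 lower. Among the 5, rCG53589 rose 3.96-fold (adjusted p = 0.0368), rCG27159.1 rose 4.01-fold (adjusted p = 0.0416) and rCG24755 fell 4.99-fold (adjusted p = 0.0416). In the fit without the block, the log2 change of rCG27159.1 was 0.98 without the 3 control arrays of contradicting labels. That fit sets SD control replicate 1 alone against the I/R arrays of all 3 runs. Within the runs its changes were 1.49, 2.14 and 2.38. All 4 changed in the same direction in each of the 3 runs. The responses of the 3 SD replicates correlated at r = 0.442, 0.422 and 0.332 across the same 7076 probes. That of SD replicate 3 correlated more closely with those of BN replicates 1 and 2, at 0.568 and 0.595, but at -0.00749 with that of BN replicate 3. The call of rCG37666 was lost with the assay-normalized signal, in the value table as deposited or put back, with only its own groups, without the 2 or 3 control arrays of contradicting labels, without any 1 of the replicate numbers, without any 1 of the SD control arrays, without SD I/R replicate 1 or 3 and without BN control replicate 3. With the block, the SD count was 139 without the BN I/R array of replicate 3, 120 without both BN arrays of replicate 3 and 8 without replicate 3 in all groups. The fits with 139 and 120 left out no SD array. All groups share 1 residual spread and the run effects, so BN arrays bear on the SD count. The 139 and the 120 included the 5, and the 8 included none of them. It was 0 without replicate 1 (1673 at an unadjusted p under 0.05) or 2 (1224), and without BN control replicate 1 or 2, BN I/R replicate 1, SD control replicate 1 or 2, or SD I/R replicate 1. The count was 1 without BN I/R replicate 2 or SD I/R replicate 3, and 2 without BN control replicate 3 or SD I/R replicate 2.

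None of the named genes changed detectably in either strain. Ramp2 gave a log2 change of 0.42 ± 0.58 (SE) in BN and 0.69 ± 0.58 in SD, Cebpb -0.21 ± 0.45 and 0.08 ± 0.45, and Itgae -0.37 ± 0.39 and -0.06 ± 0.39. Atf4 gave 0 ± 0.29 and -0.17 ± 0.29, Klk1b3 -0.09 ± 0.55 and 0.06 ± 0.55, and Hbb-b1 -0.16 ± 0.72 and 0.01 ± 0.72. The direction of Atf4 and Itgae in SD turned with the assay-normalized signal.

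**Figure D3:**
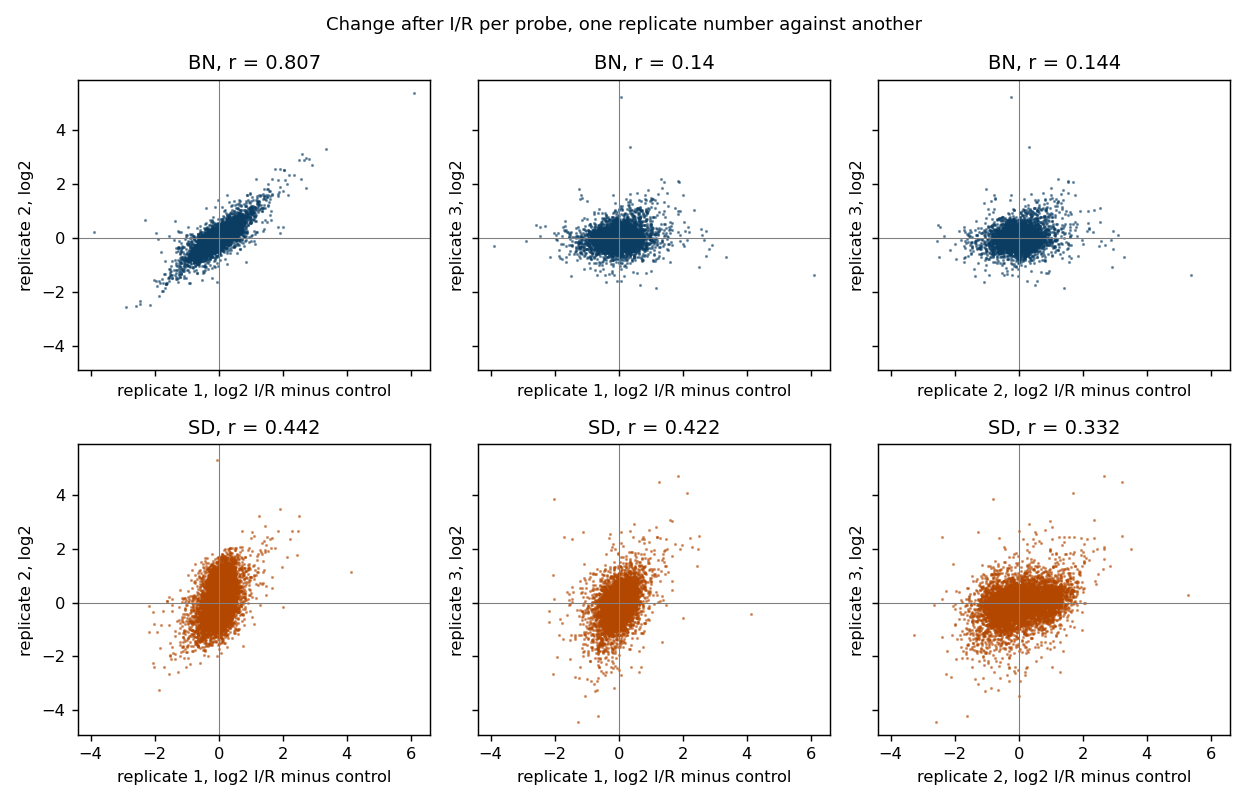
Log2 change after I/R of each of 7076 probes in 1 replicate number (horizontal axis) against another (vertical axis), for BN (top) and SD (bottom); each point is a probe. In BN the points of replicates 1 and 2 follow a line (r = 0.807) and those of replicate 3 do not (r = 0.14 and 0.144), while in SD r lies between 0.332 and 0.442.

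The question in the series title, whether the strains responded differently, was tested by the interaction of strain and I/R. No probe passed by limma, with 262 at an unadjusted p under 0.05, nor with the replicate block, with 867. The rCG35693 probe was singled out after its values were seen, as that with the smallest interaction p among 3 probes lower in every BN run and higher in every SD run by at least 0.5 on the log2 scale. It went from 11.62 ± 0.09 to 10.44 ± 0.51 in BN and from 9.67 ± 0.23 to 11.1 ± 0.28 in SD (SD, n = 3). Its response differed by -2.61 ± 0.46 (SE), with an adjusted p of 0.746, 0.0894 with the block and 0.0258 with the block as a random effect, the lowest over its alternatives, of which the highest was 1. The interaction was -0.31 ± 0.56 for Itgae, -0.29 ± 0.64 for Cebpb, -0.27 ± 0.82 for Ramp2, 0.16 ± 0.42 for Atf4, -0.16 ± 1.01 for Hbb-b1 and -0.15 ± 0.78 for Klk1b3. The value for Atf4 was -0.11 with median scaling and -0.14 with the assay-normalized signal.

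The log2 changes of the 2 strains correlated at a Pearson r of 0.344 and a Spearman rho of 0.286 across the 15401 probes, which are not independent replicates. Within runs, over all 15401 probes, r was 0.147, 0.255 and 0.0221. Across the 7076 probes with a signal-to-noise score of at least 5 on every array, the mean changes of the strains correlated at 0.545. On these probes the responses of BN replicates 1 and 2 correlated with those of the SD replicates at 0.284 to 0.595, and that of BN replicate 3 at -0.00749 to 0.195. The strains share no control arrays. The 7 and 5 probes called with the block had none in common. Independent lists would share 0.00123 in the same direction, so lists this short cannot show a difference between strains. Of the called probes named above, all but rCG24755, level in BN at 14.53 and 14.52, moved in the same direction on average in the other strain. For example, rCG20852 went from 11.41 to 9.7 in SD, where no I/R array detected it, so this fall can be understated. In BN, rCG37666 went from 11.84 to 10.91, detected on 2 of 3 I/R arrays. The Pearson r of 0.344 became 0.0262 in the value table as deposited, and 0.391 with the 2 exchanged control columns put back.

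**Figure D4:**
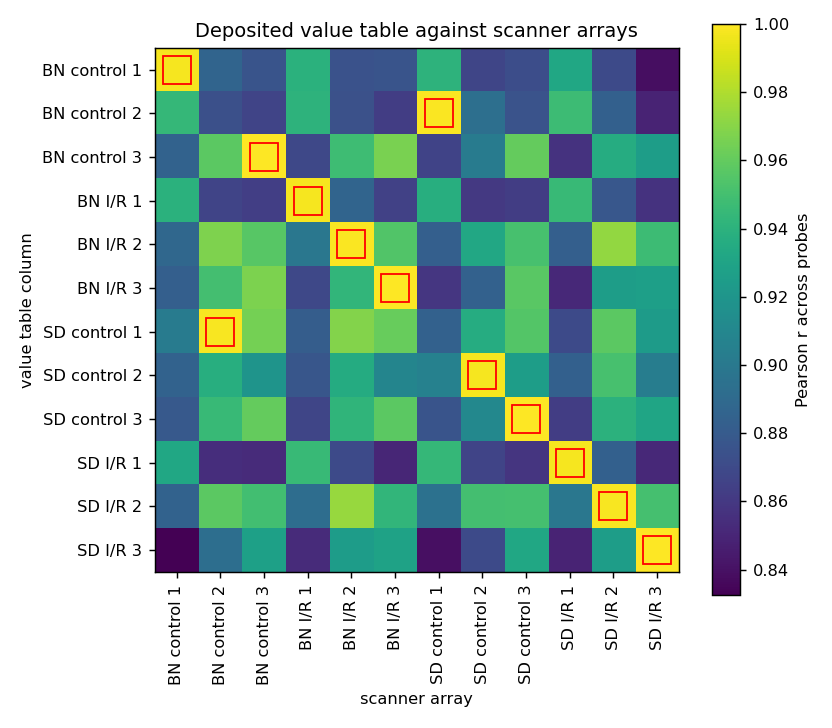
Pearson r across probes between each column of the deposited value table (vertical axis) and the log2 signal of each scanner array (horizontal axis); colour gives r, and a red square marks the best match in each row. The match lies on the diagonal for 10 columns, while BN control replicate 2 and SD control replicate 1 match each other's array.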

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

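The tests on these patterns were chosen after the values had been seen, except the counts over other splits of the arrays. Groups of 3 arrays were not tested for outlying samples by Dixon's ratio.

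The rCG35693 probe differed in its response by -2.61 on the log2 scale, as it was lower after I/R in all 3 BN runs and higher in all 3 SD runs. It was found by a search for such opposite movement, which was not tested apart from the interaction, and that did not pass (adjusted p = 0.746, or 0.0894 with the replicate block). The rCG27356 probe had an interaction of 2.35 ± 0.26 (SE) with the replicate block and the robust trend, an adjusted p of 0.0277. Its changes were 0.6, 0.95 and 0.89 in the BN runs and -1.35, -1.93 and -1.36 in the SD runs. Without the robust trend the adjusted p was 0.193, and 1 without the block.

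The response of BN replicate 3 stood apart from those of BN replicates 1 and 2, but exchanged labels of its 2 arrays would turn its changes, and the correlation was 0.14 at the lowest (although exchanging them in the additive fit gave 42 probes after I/R against 31). A low yield is argued against too, since the poorer BN array of replicate 3 detected 13016 probes, more than either BN array of replicate 1. I/R tissue on its control array, whose source name says I/R as that of SD control replicate 3 does, is argued against by 41 probes changed at least 2-fold alike in replicates 1 and 2 of both strains, among the 7076 with a signal-to-noise score of at least 5 on every array: in replicate 3 the BN control lay 0.07 from the SD control (median signed log2, 95% bootstrap interval -0.04 to 0.25), while SD responded by 1.83 and BN I/R lay -1.53 from SD I/R. That the I/R array of replicate 3 may hold control tissue stays open. The 61 of the 7076 that changed at least 2-fold in every SD run had medians of 1.47 and 1.54 in BN replicates 1 and 2. In replicate 3 their median was 0.1 (-0.07 to 0.21). The 183 that changed at least 2-fold alike in BN replicates 1 and 2 had 0.2 there (0.11 to 0.28), with 20 by 2-fold alike and 4 oppositely. For these 183, the SD control minus the BN control of replicate 3 gave 0.03 (-0.06 to 0.14), with 14 alike and 8 oppositely. The probes rCG21543 (2.23) and rCG20852 (-2.99), chosen for changes over all 3 runs, changed in full. The intervals in this paragraph are over probes, which are not independent, and do not cover differences between animals. Hence 1 pair of arrays cannot part a small response from a difference between animals. Whether replicates 1 and 2 are repeat arrays of the same BN RNA also cannot be told apart, since their correlation exceeded that with replicate 3 by 0.66 in BN but by 0.02 in SD, and a milder response of 1 animal is untested.

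The value table columns of the control arrays BN replicate 2 and SD replicate 1 matched each other's scanner array. An exchange of their values in the table is consistent with the correlations of 0.9993 and 0.9985 with the other's array, against 0.8735 and 0.8846 with their own. Wrong scanner names are argued against by 20 probes that separate the strains by at least 2-fold on the other 10 arrays, of which 20 and 18 (90%) lay nearer the strain the scanner array is named for. Of the values deposited for these 20 probes, 2 and 0 did. No biological explanation was tested.

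The replicate number held most of the variance. Weak signals are argued against as the source, as its share was 64.7% among the 7076 probes with a signal-to-noise score of at least 5 on every array, against 21.2% between groups. Quantile normalization is argued against as well, since its share was 56.9% with median scaling. The run marks in the scanner headers differ between the runs, and the labels name no other difference between them. Differences between animals handled together are untested.

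Over other splits of the 6 arrays compared, 10 are possible, too few for a share under 0.05. The BN response gave 0 probes in all 10. For the SD response the real count was 1 and the highest other 0, for the strains in controls 15 and 0, and for the strains after I/R 7 and 0; in each, 1 of the 10 splits gave as many. With the replicate block, 4 splits part the same 3 pairs, again too few. The real counts were 7 for BN, 5 for SD, 70 for the strains in controls and 38 after I/R, and the highest other was 0 each time, so 1 of the 4 gave as many. For the interaction the real count was 0, which all 100 drawn splits and, with the block, all 32 exchanges of strain within runs must reach, so they say nothing about chance. The highest other counts were 3185 and 215. The split with 3185 put 2 arrays of replicate 1 among the controls of 1 strain and none among its I/R arrays. Whether this accounts for its count was not tested.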

How the results depend on the processing

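Alternatives were planned before the data were examined except where stated here, and the value table put back was chosen after seeing the data. In the value table as deposited 2 control columns of opposite strains appear exchanged, which mixes the control groups in every fit to it. Calls lost or directions turned there therefore do not test the results. The run mark coincides with the replicate number and gave no separate block. The gene lists gave no value under any alternative because none held 5 measured genes. What follows counts probes past an adjusted p of 0.05 by limma, and the cause of a difference was not tested except where fewer arrays or probes entered. The BN response (0) gave 1 among the 8206 probes detected on all 12 arrays, 114 with array weights, 7 with the replicate block and 5 with the block random; it was 0 without any array or replicate. The SD response (1) gave 0 with the assay-normalized signal, 0 in the value table, as deposited or put back, 0 with only its own groups, 0 without the control arrays of contradicting source name, 2 with array weights, 5 with the replicate block and 58 with the block random, and 0 to 2 when an array or replicate was left out. The interaction (0) gave 2 with the block random. The strain difference in controls (15) gave 9 with the assay-normalized signal, 0 in the value table as deposited and 13 with it put back, 10 of them among the 15. It gave 0 among probes detected on all arrays, 35 with array weights and 4 with only its own groups. With the replicate block it gave 70, with the block random 102, and without the 2 control arrays of contradicting source name 5. It gave 0 to 17 when an array or replicate was left out. The strain difference after I/R (7) gave 0 in the value table as deposited and 7 with it put back, 6 of them among the 7 first called. It gave 3 among probes detected on all arrays, 202 with array weights and 2 with only its own groups. With the replicate block it gave 38, with the block random 78, and when an array or replicate was left out 0 to 9. The following were chosen after seeing the data and keep the replicate block. BN (7) gave 17 with the robust trend, 3 with median scaling, 20 among probes detected on all arrays, 620 with array weights, 0 in the value table as deposited, 71 without both BN arrays of replicate 3 and 0 to 126 when an array or replicate was left out. SD (5) gave 120, 22, 141, 2 and 0 in the same order, 24 in the value table with the columns put back, 120 without both BN arrays of replicate 3 and 0 to 139 when an array or replicate was left out. The interaction (0) gave 1 with the robust trend, 2 among probes detected on all arrays, 5 with array weights, 2 in the value table put back and 0 to 1 when an array or replicate was left out. The strains in controls (70) gave 150 with the robust trend, 131 among probes detected on all arrays, 0 in the value table as deposited, 118 with it put back, 24 without both BN arrays of replicate 3 and 0 to 63 when an array or replicate was left out. The strains after I/R (38) gave 109, 81, 959 with array weights, 0 in the value table as deposited, 56 with it put back, 19 without both BN arrays of replicate 3 and 0 to 39. The additive fit of 6 arrays against 6 gave, in place of 238 probes between strains, 439 with the robust trend, 137 without both BN arrays of replicate 3 and 14 to 85 when a replicate was left out, and in place of 31 after I/R, 337, 367 and 0 to 177. The array weights ran from 0.204 for SD control replicate 2 to 4.96 for SD I/R replicate 2 in the blocked fit. The correlation of the strains' responses (0.344) was 0.0262 in the value table as deposited, 0.532 among probes detected on all arrays and 0.218 to 0.299 without a replicate. Of 1393 values of single probes under the alternatives, 1234 kept direction and side of the threshold, 50 lost the call, 19 gained one and 90 changed direction, 0 of these past the threshold. Log2 values that changed direction in the value table as deposited were 0.59 for Hbb-b1 and 0.71 for Klk1b3 in the BN response, -0.12 for Cebpb, -0.76 for Klk1b3 and -0.72 for Hbb-b1 in the SD response, -0.17 for Atf4, 0.11 for Cebpb, 0.91 for Ramp2, 1.47 for Klk1b3 and 1.32 for Hbb-b1 in the interaction, and -0.32 for Klk1b3, -0.47 for Ramp2 and -0.76 for Hbb-b1 between control strains. With array weights they were 0.04 for Klk1b3 in BN, -0.09 for Cebpb and 0.18 for Itgae in SD, and 0.12 for Cebpb between control strains. Without the 2 control arrays of contradicting source name they were 0 for Klk1b3 and 0.02 for Atf4 in BN, and -0.15 for Hbb-b1 and 0.08 for Itgae in SD. Without the 3 control arrays they were 0 for Klk1b3 and 0.02 for Atf4 in BN, 0.04 for Itgae in the interaction and 0.19 for Cebpb between control strains. With the assay-normalized signal they were 0.11 for Atf4 and 0.09 for Itgae in SD, -0.14 for Atf4 in the interaction and 0.2 for Cebpb between control strains. With median scaling they were -0.11 for Atf4 in the interaction and 0.1 for Cebpb between control strains, and in the value table put back 0 for Itgae in SD. When arrays or replicates were left out, the BN response ran from -0.13 to 0.08 for Atf4, -0.96 to 0.48 for Hbb-b1 and -0.43 to 0.3 for Klk1b3. The SD response ran from -0.38 to 0.08 for Atf4, -0.35 to 0.38 for Cebpb, -0.43 to 0.59 for Hbb-b1, -0.5 to 0.41 for Itgae and -0.45 to 0.52 for Klk1b3. The interaction ran from -0.03 to 0.41 for Atf4, -0.61 to 0.13 for Cebpb, -0.85 to 0.48 for Hbb-b1, -0.57 to 0.09 for Itgae, -0.55 to 0.36 for Klk1b3 and -0.84 to 0.08 for Ramp2. Between control strains Cebpb ran from -0.3 to 0.24. After I/R the strain difference ran from -0.67 to 0.06 for Cebpb, -0.02 to 1.04 for Hbb-b1, -0.06 to 0.35 for Itgae and -0.03 to 0.77 for Ramp2. Of the tested values, 1.17% lay at the floor, where no difference can be ranked.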

Other observations

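All comparisons and tests in this part were chosen after seeing the data, except the counts over exchanged labels. With strain, condition and replicate number as additive terms, 6 arrays against 6, 238 of 15401 probes differed between the strains by limma, 131 higher and 107 lower in BN. Of the 32 exchanges of strain labels within runs and conditions, only the real one (1 of 32) gave as many, and the highest other gave 1. That is the smallest share 32 exchanges can give, and it counts the exchanged pairs as independent. As BN replicates 1 and 2 may be repeat arrays of the same RNA, chance was not excluded. Klk1b3 was the only one of the 13 named genes tested to be among the 238, with a log2 difference of 1.24 ± 0.2 (SE; limma adjusted p = 0.0184, 0.00311 to 0.21 over the alternatives), and was higher in BN in all 6 pairs of the same run and condition. Its call was lost without replicate 1, 2 or 3 (adjusted p = 0.135, 0.21 and 0.0777) and without both BN arrays of replicate 3 (0.115). In the same fit 31 probes changed after I/R over both strains, 17 higher and 14 lower. Chance was not excluded for this count either, as 2 of the 32 exchanges of condition labels gave as many and the highest other gave 42. That exchange turned the condition labels of the 2 BN arrays of replicate 3. The counts were 238 and 31 with all arrays, 137 and 367 without both BN arrays of replicate 3, and 85 and 177 without replicate 3 in all groups. Without replicate 1 they were 52 and 0, and without replicate 2 they were 14 and 0.

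Detection itself separated the strains for a few probes. This too concerns probe signal, and transcript levels were not tested by another measure. On all 6 BN arrays and no SD array, 2 probes were detected, and 7 on all 6 SD arrays and no BN array. The probe rCG25170 was at least 25.4-fold higher in BN over both conditions, and rCG60219 at least 7.81-fold higher in SD. Among 108 splits of the 12 arrays into groups of 6 balanced over the runs, the highest other split gave 3 such probes against the 9 seen.

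Changes of at least 2-fold in the same direction in all 3 runs were seen after I/R for 62 probes upward and 23 downward in BN, and for 180 upward and 86 downward in SD. With the sign of 1 run turned, the total of 85 in BN became 10, 12 or 52, and the total of 266 in SD became 22, 13 or 38. For the BN response minus the SD response the total was 165, and it became 62, 84 or, with replicate 3 turned, 203, more than the real total. Probes that moved by at least 0.5 in opposite directions in the strains in every run numbered 17 for higher in BN and lower in SD, and 3 for the reverse. At any size they numbered 279 (1.81%) and 195 (1.27%). Independent random signs would give 1.56%, but the responses correlated between runs and strains, so nothing is concluded from that value.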
